A study of Mus musculus with 8 samples.

How the data were processed

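Single-cell RNA sequencing was done on mouse CD8 T cells that had been grown with bone marrow stromal cells (BMSCs) carrying dsRed in their mitochondria. T cells with dsRed (MitoPositive) and without it (MitoNegative) were separated before sequencing or transfer, so at d7 both names refer to the state at transfer. The data hold 4 libraries with 18 hashtagged samples from 3 donor mice: 6 samples in 1 library at d0, and 12 samples in 3 libraries (1 per donor) from spleen and tumor 7 days after transfer. Per the file headers, the deposited matrices are UMI counts written by Cell Ranger 7.0.0. The submitters' processing notes name Cell Ranger 7.0.0, Seurat 4.0.5 and the genome build mm10 (GRCm38). The deposited matrices hold counts for 32285 genes and for the hashtags, are not normalised and are not divided by hashtag. A deposited list gives the authors' counts of sorted cells, without saying how they were counted.

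The labels gave conflicting maps of the d0 hashtags: odd against even numbers in the series design, and 1 to 3 against 4 to 6 in the extraction protocol. The deposited readme and hashtag list both gave odd numbers to MitoPositive cells, and that map was used, with the other as an alternative. The deposited list also assigned the hashtags to donors and showed that, at d7, MitoPositive and MitoNegative cells of a donor came from different recipient mice, whereas spleen and tumor cells of 1 arm came from the same recipients. Donor therefore pairs the samples. Deviations from the group means correlated across genes at 0.03 to 0.65 for samples of the same donor at d0 and at -0.15 to 0.55 at d7, against -0.65 to 0.24 and -0.56 to 0.35 for different donors.

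Barcodes with at least 500 genes and less than 15% mitochondrially encoded UMIs were kept. The plan fixed before the data were examined assigned barcodes to hashtags with HTODemux (Seurat 5.3.0, positive quantile 0.99). That caller left 51.7% of barcodes of the donor 1 library and 27.0% of the donor 2 library without a hashtag, although 0.115% and 0.0613% had a top hashtag under 10 UMIs. The plan was therefore left at this step, from the hashtag counts and before any gene was tested: a barcode was assigned to its highest hashtag if that had at least 10 UMIs and at least 3 times the UMIs of the next. The callers gave the same result for 91.5% of barcodes at d0 and for 34.8%, 60.5% and 94.0% in the libraries of donors 1, 2 and 3. HTODemux became the alternative, and its counts stand beside the results they move. After filtering, HTODemux left 79, 81 and 105 cells in the MitoNegative tumor samples of donors 1, 2 and 3, against 30, 85 and 116. In the MitoNegative spleen sample of donor 1 it left 527 cells against 3417. Leiden clusters (scanpy 1.11.5, leidenalg 0.10.2, 2000 variable genes, 30 principal components, resolution 0.5) were made per day, and 2 clusters in which fewer than 50% of cells had a Cd3d, Cd3e or Cd3g UMI were left out.

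UMIs were summed per hashtagged sample, and samples, not cells, were the replicates. A sample needed at least 20 cells, which was met in every fit but that of Trbv14 cells, where 2 samples of 18 cells were kept. From 18092 barcodes, 16338 cells entered the sums, with 30 to 3417 cells and 323344 to 26560592 UMIs per sample. Genes were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The d0 samples were fitted alone and without a donor term. The d7 contrasts came from 1 fit of 12 samples with library (donor) as a block, and the difference between days from a fit of 18 samples with the block at d7. Standard errors of log2 fold changes were derived from the F statistic. On simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, the fits recovered 90% and 100% at d0 (11436 genes), 49% and 84% in the tumor, 63% and 94% in the spleen, 68% and 97% between tissues, 25% and 74% for the difference between tissues (11951 genes each), and 66% and 87% for the difference between days (12801 genes). Between 7 and 18 unchanged genes were called per simulation. These were 13 at d0, 16 in the spleen, 18 between tissues, 12 for the difference between tissues and 11 for the difference between days. Each of these was a share above 0.05 of the calls. The simulated counts held no donor effects and the same base level in every group.

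Gene lists were fixed before the data were examined: 31 lists, covering the S and G2/M phases, glycolysis, the tricarboxylic acid cycle, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, mitochondrial biogenesis and import, mitochondrial dynamics and transport, fatty acid oxidation, cholesterol synthesis, antioxidant genes, integrated stress and unfolded protein response, dissociation stress, ribosomal proteins, stem and memory, effector, exhaustion, tissue residency, immediate early T cell receptor, interferon response, chemokine and adhesion and apoptosis genes, and markers of CD8 T, CD4 T, NK and γδ T, B, myeloid, stromal, melanoma, endothelial and erythroid or platelet cells. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation and with fry. Named genes were the 10 with the largest positive and the 10 with the largest negative log2 fold change among called genes with a mean log2 CPM of at least 5 and the same direction in each donor (at d0, no overlap of the groups, which chance gives 10% of genes). Predicted gene models were left out. Of the genes that met the rule, 1 is not reported here, and it was kept in all fits and counts. With no call, the 3 genes with the smallest p per direction were named, and list members were taken from the 4 with the smallest p. Gene positions came from GENCODE vM21 by gene identifier. Single values per sample were compared with two-sided exact permutation tests, which cannot go below 0.1 with 3 samples per group.

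Alternatives were DESeq2 size factors and the DESeq2 1.42.0 Wald test, no count filter, HTODemux, no mitochondrial limit, all clusters, cells thinned to 2000 UMIs with equal cell numbers per sample, each replicate left out, the donor block added or removed, the other hashtag map, and tumor or spleen samples alone. Further alternatives were chosen after seeing the data: without clusters led by genes of other cell types, without clusters of low UMI number, without cycling clusters, only cells with a Trbv14 UMI and no UMI of another Trbv segment, the same without samples that held fewer than 20 such cells, and the set of recipient mice as the block for contrasts within recipients.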

Results

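The data describe CD8 T cells of 3 donor mice that did or did not carry dsRed-labelled mitochondria after culture with BMSCs. The cells were profiled directly (d0) or 7 days after transfer into mice bearing B16KVP tumors. Each of the 6 groups held 3 samples, 1 per donor. Median depth per library was 7400 UMIs per barcode at d0 and 6858, 5900 and 8814 in the d7 libraries of donors 1, 2 and 3. MitoPositive samples held 937 to 1025 cells at d0, 49 to 2281 in the spleen and 172 to 995 in the tumor. MitoNegative samples held 823 to 951, 541 to 3417 and 30 to 116 cells. The authors' numbers of sorted tumor cells were 528, 2800 and 2900 for MitoPositive and 124, 274 and 749 for MitoNegative cells of donors 1, 2 and 3, ratios of 4.26, 10.2 and 3.87. Their spleen numbers had ratios of 0.4, 2.11 and 0.0803. Within each donor, the 2 d7 arms came from different recipient mice, so effects of the recipients and of the MitoPositive state cannot be separated there.

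At d0, the first comparison asked how T cells that had taken up mitochondria differed from those that had not. Cell cycle RNA was higher in MitoPositive cells: all 22 measured genes of the G2/M list rose (22 adjusted over the list alone), with a median log2 fold change of 1.59. Mki67, a proliferation marker, rose by 1.66 ± 0.18 (SE, n = 3 per group, adjusted p = 0.00023), from 25.2 ± 7.89 to 77.6 ± 13.8 CPM (SD), Top2a, a topoisomerase of dividing cells, by 1.40 ± 0.14 (adjusted p = 0.00021), and Hmmr by 1.81 ± 0.22 (adjusted p = 0.00043). Of 21 S phase genes, 14 rose (18 adjusted over the list alone), with a median of 0.66, among them Rrm2, a subunit of ribonucleotide reductase, at 1.94 ± 0.21 (adjusted p = 0.00023). The stem and memory list went the other way, with 9 of 18 genes lower and 1 higher (13 and 1 adjusted over the list alone) and a median of -0.39. Klf3 fell by 1.89 ± 0.23 (adjusted p = 0.00045) and Klf2, a regulator of T cell trafficking, fell by 1.72 ± 0.28 (adjusted p = 0.002). Cluster 4 of the d0 clustering was the largest among MitoNegative cells in each donor and among MitoPositive cells in none, so the values compare cells of different clusters. The planned tests of cluster shares were not run at d0, since genes that lead this cluster, among them Klf2, Klf3 and Dapl1, also differed between the arms.

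By camera, the adjusted p was 8.8e-39 for the G2/M list, 7.3e-19 for the S phase list and 1.9e-10 for the stem and memory list, but each was 0.33 as an adjusted p with an estimated correlation. Glycolysis genes rose for 11 of 18 members (13 higher and 1 lower adjusted over the list alone), with a median of 0.30 and a camera adjusted p of 6.3e-09 (adjusted p = 0.33 with an estimated correlation). Pgk1 stood at 0.71 ± 0.10 and Aldoa, also a glycolytic enzyme, at 0.57 ± 0.08. The integrated stress list had 6 of 16 genes higher (7 adjusted over the list alone), including Psat1, a serine synthesis enzyme, at 0.91 ± 0.19, with a camera adjusted p of 4.1e-04 (adjusted p = 0.68 with an estimated correlation). Nuclear oxidative phosphorylation genes had positive fold changes for 67 of 75 members, a median of 0.14 and 3 calls (2 adjusted over the list alone), with a camera adjusted p of 2.7e-05 (adjusted p = 0.78 with an estimated correlation). None of the 13 mitochondrially encoded genes passed by edgeR (0 adjusted over the list alone), and their summed share was 2.68% ± 0.037 against 2.54% ± 0.13 of UMIs (SD, n = 3, exact p = 0.2), higher in 3 of 3 donors. Without the mitochondrial limit, which removed 3.87% of MitoPositive and 1.47% of MitoNegative cells, it was 2.82% ± 0.058 against 2.59% ± 0.15 (exact p = 0.1, the smallest possible). It was higher in 2 of 3 donors with HTODemux (exact p = 0.2) and without clusters of low UMI number (exact p = 0.4). The list's median of -0.02 was negative, and its mean of 0.02 and camera statistic were positive.

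Across all 11436 genes tested at d0, edgeR called 690 higher and 369 lower, 1059 in all, and 2295 with the donor block. The other named genes with higher RNA were Pclaf, Stmn1, AI506816, Cenpf, Nusap1, Hist1h2ap, Ccnb2, Hist1h1b and Birc5, at 1.66 to 1.85, most of them cell cycle genes. Those with lower RNA were Dapl1, Fgf13, Txk, Nsg2, Ifngas1, Myb, Sidt1 and Samd3, at -1.58 to -1.15. Stromal marker RNA was 3.34 ± 1.15 CPM in MitoPositive and 3.07 ± 0.36 CPM in MitoNegative cells (SD, n = 3, exact p = 0.8). MitoPositive cells had a higher median UMI number, 7950 ± 896 against 6818 ± 823 (SD, n = 3, exact p = 0.3), higher in 3 of 3 donors. With cells thinned to equal UMIs and cell numbers, 215 genes were called, 11 of 18 G2/M genes rose with a median of 1.21, 0 of 15 S phase genes passed by edgeR with a median of 0.34, 1 of 17 glycolysis genes rose with a median of 0.15, and the median of the oxidative phosphorylation list was 0.0051. Without the cycling cluster, 622 genes were called, the G2/M median was 0.16 with 3 of 20 genes called, the S phase median 0.10 with 0 of 19 by edgeR, the glycolysis median 0.24 with 7 of 18, and the stem and memory median was -0.33 with 8 lower. The count was 1623 without a count filter. It was 495 without MitoNegative replicate 2, 512 without MitoPositive replicate 2, 561 without MitoNegative replicate 1 and 612 without MitoPositive replicate 3, and with the other hashtag map 0 genes were called by edgeR, with 393 at an unadjusted p under 0.05.

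**Figure D1:**
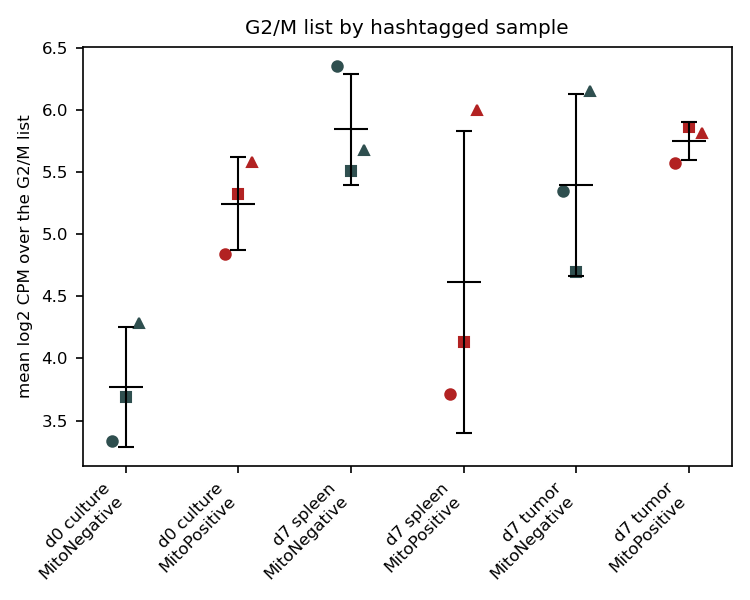
Mean log2 CPM over the 22 genes of the G2/M list (y axis) in each hashtagged sample, by group (x axis). Symbols mark donors 1 (circle), 2 (square) and 3 (triangle), bars the mean ± SD of 3 samples. MitoPositive samples were higher in 3 of 3 donors at d0.

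In the tumor at d7, Ifng, Ccl4, Ccl3 and Il2 were lower, and Klre1 and Gzmc higher, in cells that had been MitoPositive at transfer. Ifng, the interferon gamma gene, fell by 2.18 ± 0.23 (SE, n = 3 per group, adjusted p = 0.0046), from 3955 ± 1966 to 789 ± 205 CPM (SD). The chemokine genes Ccl4 and Ccl3 fell by 1.65 ± 0.31 and by 1.57 ± 0.28 (adjusted p = 0.044 and 0.041), and Il2, a T cell growth factor gene, fell by 1.56 ± 0.29 (adjusted p = 0.044). Klre1, an NK cell receptor gene, rose by 1.70 ± 0.25 (adjusted p = 0.029) and the granzyme gene Gzmc by 0.94 ± 0.16 (adjusted p = 0.031). Each of these 6 genes moved the same way in 3 of 3 donors, which the rule for named genes required. Most tumor cells lay in clusters 10 and 11 of the d7 clustering. Cluster 10 was the larger in both arms of donor 1 and in MitoNegative cells of donor 2, and cluster 11 in both arms of donor 3 and in MitoPositive cells of donor 2. Shares were not tested here either, since genes that lead these clusters, among them Ifng, Il2, Ccl3 and Ccl4 in cluster 10 and Gzmc in cluster 11, differed between the arms. Ifng (-2.45 to -1.82) passed in every alternative run. With HTODemux, Klre1 (adjusted p = 0.097), Gzmc (0.14), Ccl3 (0.15), Il2 (0.18) and Ccl4 (0.19) did not pass. Ccl3, Ccl4, Il2 and Gzmc also did not pass without replicate 1, without replicate 2 or without the donor block, nor did Klre1 without replicate 2, Ccl3 and Gzmc with tumor samples alone, Ccl3 and Il2 with thinned cells, Ccl4 and Il2 (-0.98) with Trbv14 cells (also without the samples under 20 such cells), or Gzmc without clusters led by other cell types.

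Within the fixed lists, 1 effector gene rose and 3 fell of 24 (3 and 3 adjusted over the list alone, adjusted p = 0.87 with an estimated correlation), where the median of 0.15 and mean of 0.24 were positive and the camera statistic negative. No exhaustion gene passed over all genes by edgeR, against 8 higher and 3 lower adjusted over the list alone (adjusted p = 0.87 with an estimated correlation). All 13 mitochondrially encoded genes had positive fold changes, with a median of 0.28. None passed over all genes and 12 did adjusted over the list alone, with a camera adjusted p of 3.7e-07 (adjusted p = 0.87 with an estimated correlation). Their summed share of UMIs was 2.14% ± 0.076 against 1.85% ± 0.21 (SD, n = 3, exact p = 0.2), higher in 3 of 3 donors. For markers of other cells, the myeloid list had a median of -1.61 (0 called over all genes, 7 lower adjusted over the list alone, camera adjusted p = 8e-08) and the melanoma list a median of -3.63 (0 and 8, camera adjusted p = 0.0099), each with adjusted p = 0.87 with an estimated correlation. Myeloid marker RNA was 273 ± 26.9 against 659 ± 565 CPM and melanoma marker RNA 50.5 ± 42 against 687 ± 1133 CPM (SD, n = 3, exact p = 0.4 and 0.6), lower in 2 of 3 and in 1 of 3 donors. Chemokine and adhesion genes had a median of 0.23 and mitochondrial biogenesis and import genes one of -0.15, each with 0 calls over all genes (2 higher and 1 lower adjusted over the lists alone), camera adjusted p = 0.0099 and adjusted p = 0.87 with an estimated correlation.

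In total, edgeR called 24 higher and 26 lower of 11951 genes in the tumor, or 14 and 29 with DESeq2 size factors. The remaining named genes were Pglyrp1, Airn, Il10ra, Tnfsf10, Nr3c1, Plxdc2, Eif2ak3 and Vav3, at 0.82 to 1.08, and Zbtb32, Rora and Farp1, at -1.30 to -0.84. The MitoNegative tumor samples held 30, 85 and 116 cells, and the total of 50 genes became 2 with thinned cells, 5 with HTODemux, 9 with tumor samples alone, 15, 30 and 33 without replicates 3, 1 and 2, 22 with Trbv14 cells (85 without the 2 d7 samples of 18 such cells), 171 with DESeq2 and 789 without a count filter.

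**Figure D2:**
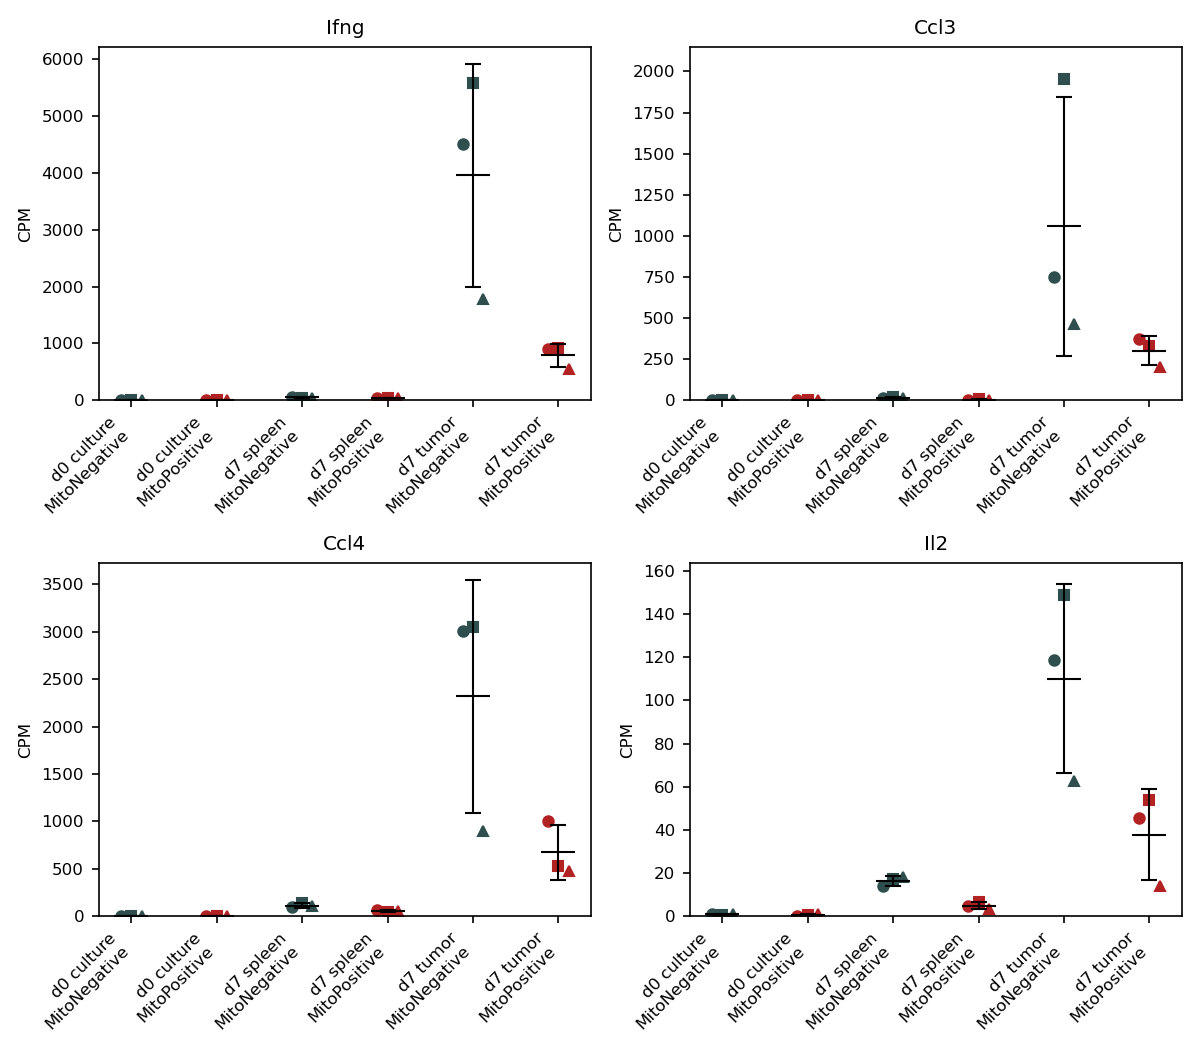
CPM (y axis, from 0) of Ifng, Ccl3, Ccl4 and Il2 in each hashtagged sample, by group (x axis). Symbols mark donors 1 (circle), 2 (square) and 3 (triangle), bars the mean ± SD of 3 samples. In the tumor the highest MitoPositive value of Ifng, 922 CPM, lay below the lowest MitoNegative value, 1772 CPM.

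In the spleen at d7, cell cycle RNA was lower in cells that had been MitoPositive at transfer. Of 22 S phase genes 17 fell (22 adjusted over the list alone) with a median of -1.37, and of 22 G2/M genes 14 fell (21 adjusted over the list alone) with a median of -1.68. Pclaf, a PCNA-binding replication factor gene, fell by 2.50 ± 0.42 (SE, n = 3 per group, adjusted p = 0.012), Tyms, thymidylate synthase, fell by 1.91 ± 0.30 (adjusted p = 0.0087) and Mki67 fell by 1.65 ± 0.32 (adjusted p = 0.019). Among genes with higher RNA were Lilrb4a, an inhibitory receptor gene, at 2.28 ± 0.27 (adjusted p = 0.0021), Klre1 at 1.92 ± 0.23 (adjusted p = 0.0021), Zeb2, a transcription factor gene of effector T cells, at 1.90 ± 0.28 (adjusted p = 0.0072), and Il2ra, an interleukin 2 receptor gene, at 1.76 ± 0.21 (adjusted p = 0.0023). The mean G2/M level in donor 3, whose MitoPositive sample held 49 cells, was 6.00 in MitoPositive and 5.68 log2 CPM in MitoNegative cells, opposite to donors 1 (3.71 and 6.36) and 2 (4.13 and 5.51). Summed G2/M RNA was 1845 ± 1204 CPM in MitoPositive and 3576 ± 998 CPM in MitoNegative samples (SD, n = 3, exact p = 0.3, not planned). It was higher in MitoPositive samples in 1 of 3 donors. In each donor, most MitoPositive spleen cells lay in clusters 4 and 5 of the d7 clustering, while cluster 2 was the largest among MitoNegative cells, so the values compare cells of different clusters. The planned tests of cluster shares were not run, since genes that lead these clusters, among them Cx3cr1, Gzmk and Zeb2, also differed between the arms.

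Camera gave an adjusted p of 3.3e-26 for the S phase and 3e-14 for the G2/M list (adjusted p = 0.5 and 0.67 with an estimated correlation). Oxidative phosphorylation genes had negative fold changes for 72 of 75 members, a median of -0.30 and 1 call, Ndufa4, a gene of the respiratory chain, at -0.60 ± 0.14 (0 adjusted over the list alone), with a camera adjusted p of 9.3e-13 (adjusted p = 0.67 with an estimated correlation). Ribosomal protein genes had a median of 0.19, with 6 of 30 higher (17 adjusted over the list alone) and a camera adjusted p of 5.8e-09 (adjusted p = 0.67 with an estimated correlation). In the effector list 5 of 24 genes rose and 1 fell (9 and 3 adjusted over the list alone, camera adjusted p = 1.7e-04, adjusted p = 0.67 with an estimated correlation), with Gzmk at 1.80 ± 0.38 and Ccl3 at -1.98 ± 0.42. Exhaustion genes went both ways, 1 higher and 3 lower of 17 (5 and 6 adjusted over the list alone): Entpd1 stood at 1.86 ± 0.19, Pdcd1, the PD-1 gene, at -1.47 ± 0.19 and Havcr2 at -1.47 ± 0.34. In the NK and γδ T cell list 3 of 6 genes rose (3 adjusted over the list alone), Klre1 and the γ chain genes Tcrg-C1 at 2.66 ± 0.42 and Tcrg-C2 at 2.46 ± 0.37, with a camera adjusted p of 1.3e-07 (adjusted p = 0.5 with an estimated correlation). Stem and memory genes had a median of 0.30, with 2 higher and 1 lower of 18 (4 and 2 adjusted over the list alone, camera adjusted p = 0.048, adjusted p = 0.88 with an estimated correlation). Cholesterol synthesis genes had a median of -0.23 with 0 called by edgeR (2 lower adjusted over the list alone, camera adjusted p = 0.025, adjusted p = 0.88 with an estimated correlation). The mitochondrially encoded share was 2.08% ± 0.22 against 2.03% ± 0.083 (SD, n = 3, exact p = 0.7).

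Over 11951 genes, 118 were higher and 274 lower in the spleen, 392 in all. The other named genes were Itga4, Tent5a, Gimap7, Fgl2, Cx3cr1 and Lrrk1, at 1.52 to 1.79, and Ccna2, Hist1h2ap, Hist1h1b, Spc24, Clspn, Rrm2, Hist1h2ae and Uhrf1, at -2.28 to -1.99. Trbv14, the T cell receptor segment that made up most Trbv RNA, was 70.9% ± 6.99 of Trbv UMIs in MitoPositive and 90.9% ± 5.76 in MitoNegative spleen samples (SD, n = 3, exact p = 0.1, the smallest possible), lower in 3 of 3 donors. It was 81.6% ± 11.9 against 84.2% ± 9.52 at d0, before transfer (exact p = 0.8), and 89.9% ± 1.51 against 92.4% ± 3.81 in the tumor (exact p = 0.4). In Trbv14 cells alone, 637 genes were called, among them 329 of the 382 first called genes that could be tested, while Cx3cr1 (0.83), Gzmk (1.00), Trbc2 (-0.090) and Id3 (-0.28) did not pass. That fit kept the donor 3 MitoPositive spleen and donor 1 MitoNegative tumor samples, with 18 such cells each, under the minimum of 20. Without both samples, 674 genes were called, among them 322 of the 387 that could be tested, and Ccl3 (adjusted p = 0.063) did not pass either. The count rested most on donor 1: without replicate 1, edgeR called 0 genes, with 756 at an unadjusted p under 0.05. It was 82 without replicate 2 and 979 without replicate 3. Without replicate 1 all 392 genes kept their direction, at a median ratio of fold changes of 0.79. Those genes had been called with the remaining donors included. The count was 5 with thinned cells, which hold 30 cells per sample, 43 with HTODemux, 64 without the cycling clusters and 590 with DESeq2. It was 930 without a count filter, 943 without clusters led by other cell types and 1022 with spleen samples alone, and thinning turned Il2ra to -0.48.

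**Figure D3:**
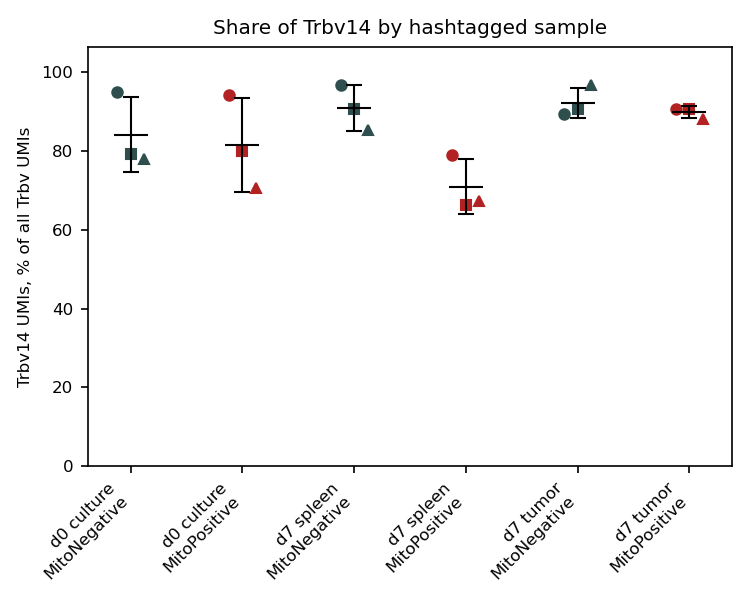
Trbv14 UMIs as % of all Trbv UMIs (y axis, from 0) in each hashtagged sample, by group (x axis). Symbols mark donors 1 (circle), 2 (square) and 3 (triangle), bars the mean ± SD of 3 samples. In the spleen the means were 70.9% for MitoPositive and 90.9% for MitoNegative samples.

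Between the organs, transferred cells differed broadly, with activation and dissociation stress genes higher in the tumor. In each sample most tumor cells lay in clusters 10 and 11 and most spleen cells in clusters 2, 4 and 5. Median UMIs per cell were 13583 ± 2924 in MitoPositive and 15176 ± 6076 in MitoNegative tumor samples (SD, n = 3). In the spleen they were 5890 ± 517 and 6759 ± 855. Depth per cell thus differed between the organs. The thinned fit, with 30 cells per sample, cannot part depth from the loss of cells. Of 17 immediate early T cell receptor genes 15 rose (15 adjusted over the list alone) with a median of 2.60, including Tnfrsf9, the 4-1BB gene, at 5.26 ± 0.15 (SE, n = 6 per organ, adjusted p = 1.5e-10). Of 13 dissociation stress genes 12 rose (12 adjusted over the list alone, adjusted p = 0.36 with an estimated correlation), including Atf3 at 6.82 ± 0.34, and no test separated the organ from the preparation of the tissue. Of 17 exhaustion genes 12 rose and 3 fell (12 and 3 adjusted over the list alone) with a median of 2.05, including Rgs16 at 6.94 ± 0.13 (adjusted p = 4.2e-12) and Ctla4, an inhibitory receptor gene, at 3.87 ± 0.10 (adjusted p = 1.1e-10). Stem and memory genes were lower for 13 of 18 and higher for 2 (13 and 2 adjusted over the list alone), with Klf2 at -3.26 ± 0.23, and interferon response genes were lower for 21 of 22 (21 adjusted over the list alone) with a median of -1.52, with Ifit3 at -2.75 ± 0.23. For the immediate early, exhaustion, stem and memory, and interferon lists camera gave adjusted p of 2.1e-18, 8.7e-18, 1.2e-06 and 6.5e-09, and adjusted p = 0.15, 0.069, 0.36 and 0.36 with an estimated correlation.

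Genes higher or lower in the tumor were also counted for metabolic and other lists, and the lists were not compared with each other. Glycolysis genes rose for 15 of 18 and fell for 2, with Hk2, a hexokinase gene, at 3.80 ± 0.17. Unfolded protein and integrated stress genes rose for 15 of 17 and fell for 1, cholesterol synthesis genes rose for 12 of 18, and oxidative phosphorylation genes rose for 55 of 75 and fell for 1 (15 and 2, 15 and 1, 12, and 55 and 2 adjusted over the lists alone). These 4 lists had adjusted p = 0.28, 0.28, 0.36 and 0.61 with an estimated correlation. Mitochondrial biogenesis and import genes rose for 19 of 28 and fell for 2, and tricarboxylic acid cycle genes rose for 8 of 17 and fell for 1 (19 and 2, and 8 and 1 adjusted over the lists alone). Fatty acid oxidation genes rose for 6 of 14 and fell for 2, and mitochondrially encoded genes rose for 3 of 13 (6 and 2, and 3 adjusted over the lists alone). The medians of these 4 lists were 0.69, 0.22, 0.20 and 0.11, with camera adjusted p of 1e-05, 0.067, 0.67 and 0.26 (adjusted p = 0.36, 0.61, 0.86 and 0.85 with an estimated correlation). S phase genes rose for 20 of 22 (20 adjusted over the list alone, camera adjusted p = 7.4e-05, adjusted p = 0.61 with an estimated correlation). G2/M genes rose for 8 of 22 (7 adjusted over the list alone, median 0.50, camera adjusted p = 0.31, adjusted p = 0.91 with an estimated correlation). Ribosomal protein genes rose for 27 of 30 (27 adjusted over the list alone), and tissue residency genes rose for 5 of 9 and fell for 3 (5 and 3 alone). Chemokine and adhesion genes rose for 3 of 14 and fell for 10 (3 and 10 adjusted over the list alone), and effector genes rose for 8 of 24 and fell for 9 (8 and 9 alone). These 4 lists had camera adjusted p of 2.9e-06, 2.1e-04, 0.011 and 0.02 (adjusted p = 0.49, 0.36, 0.61 and 0.61 with an estimated correlation). Of the markers, CD8 T cell genes fell for 7 of 10 and rose for 1 (7 and 1 adjusted over the list alone), and B cell genes fell for 3 of 4 (3 alone). Myeloid genes fell for 7 of 16 and rose for 1 (7 and 1 adjusted over the list alone), and NK and γδ T cell genes fell for 4 of 6 and rose for 1 (4 and 1 alone). These 4 marker lists had camera adjusted p of 0.046, 0.08, 0.12 and 0.25 (adjusted p = 0.61, 0.40, 0.68 and 0.68 with an estimated correlation). Overall edgeR called 3492 higher and 3714 lower of 11951 genes, 7206 in all and 477 with thinned cells. The named genes were Ccl1, Gzmc, Igfbp7, Xcl1, Nrgn, Csf2, Ccl3, Spp1 and Cd83, at 5.62 to 7.44, and Dtx1, Rap1gap2, Cd7, Nsg2, Arhgef18, Hsd11b1, Klf3, Ifi208 and S1pr1, at -4.77 to -3.19.

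Whether the MitoPositive effect differed between tumor and spleen was tested directly. Il2ra stood at -1.80 ± 0.27 (tumor effect minus spleen effect, SE, n = 3 per group, adjusted p = 0.051), Zeb2 at -2.50 ± 0.40 (adjusted p = 0.064) and St3gal6 at -1.62 ± 0.30 (adjusted p = 0.081). Capg stood at 1.40 ± 0.19, Tnfsf10, the TRAIL gene, at 1.29 ± 0.19, and Plxnc1 at 1.69 ± 0.25 (adjusted p = 0.051 each). All 22 S phase and all 22 G2/M genes had positive values, with medians of 1.57 and 1.80, of which 0 and 0 passed over all genes and 21 and 17 adjusted over the lists alone (camera adjusted p = 1.7e-26 and 9.4e-14, adjusted p = 0.65 each with an estimated correlation). The mean G2/M level of donor 3 went against that median. It was 5.815 in MitoPositive and 6.16 log2 CPM in MitoNegative tumor cells, and 6.00 and 5.68 log2 CPM in the spleen. All 16 myeloid genes, all 9 melanoma genes and all 6 NK and γδ T cell genes had negative values, with medians of -1.63, -4.46 and -1.06. In the tumor, donors differed. Melanoma marker RNA, 50.5 ± 42 against 687 ± 1133 CPM (SD, n = 3), was higher in MitoPositive samples in 2 of 3 donors, and myeloid marker RNA in 1 of 3. Of the genes in these 3 lists, 0 were called by edgeR over all genes, and 5, 1 and 0 were lower adjusted over the lists alone (camera adjusted p = 2.8e-07, 0.009 and 0.0026, adjusted p = 0.65, 0.74 and 0.65 with an estimated correlation). Values were positive for 71 of 75 oxidative phosphorylation, 17 of 18 cholesterol synthesis and 13 of 13 mitochondrially encoded genes, and negative for 27 of 30 ribosomal protein genes, 13 of 24 effector genes and 9 of 18 stem and memory genes. For these 6 lists, camera adjusted p was 3.3e-09, 0.0026, 0.0057, 1.3e-04, 0.0026 and 0.042 (adjusted p = 0.74 each with an estimated correlation). They had 0 calls by edgeR over all genes. Adjusted over the lists alone, 1 cholesterol synthesis gene was higher, and 1 effector gene was higher and 3 were lower. By edgeR 0 genes passed, with 1611 at an unadjusted p under 0.05 where 598 would be there by chance. That fit had the donor as the block, while spleen and tumor cells of 1 arm came from the same recipients. With the set of recipients as the block, chosen after the result was seen, 1 gene was higher and 2 were lower, 3 in all, with 1231 at an unadjusted p under 0.05. DESeq2 size factors moved the median of all genes from 0.083 to -0.022. DESeq2 called 157 genes, and edgeR called 876 without a count filter, 420 without replicate 3, 91 without clusters led by other cell types, 7 without the donor block, 4 without the mitochondrial limit and 1 with thinned cells.

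Whether the MitoPositive effect differed between d7 and d0 was also tested. Of 22 G2/M genes 21 had a lower effect at d7 (22 adjusted over the list alone), with a median of -2.40 and Mki67 at -2.34 ± 0.36 (SE, n = 3 per group, adjusted p = 0.0012). Of 22 S phase genes 14 had a lower effect at d7 (20 adjusted over the list alone), with a median of -1.25, and 6 of 18 stem and memory genes a higher one (8 adjusted over the list alone), with Klf2 at 1.68 ± 0.42 (adjusted p = 0.024). Camera gave adjusted p of 1.5e-22, 8.2e-19 and 6.3e-06 for the 3 lists (adjusted p = 0.57 each with an estimated correlation). The effect was also lower at d7 for 3 of 75 oxidative phosphorylation, 5 of 18 glycolysis and 5 of 18 integrated stress genes (24, 10 and 5 adjusted over the lists alone), with medians of -0.30, -0.47 and -0.51. Camera gave adjusted p of 9.7e-11, 1.1e-04 and 7.9e-04 (adjusted p = 0.83, 0.57 and 0.57 with an estimated correlation). Here the d7 effect was the mean of the spleen and tumor effects. In the tumor alone, the G2/M and S phase medians were 0.18 and 0.17, with 17 and 18 of 22 genes positive. They were -1.68 and -1.37 in the spleen. In the tumor 0 genes of either list were called by edgeR (camera adjusted p = 0.18 and 0.096, adjusted p = 0.87 each with an estimated correlation). Klf2 was 52.1 against 77.6 CPM in the tumor and 694 against 555 CPM in the spleen (MitoPositive against MitoNegative, n = 3). In all, 287 genes had a higher and 534 a lower effect at d7 of 12801 tested, 821 together, against 385 with HTODemux, 6 with thinned cells and 309, 279 and 337 without replicates 1, 2 and 3.

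Of the genes higher at d0, 165 were lower in the spleen, where independent lists would share 15.7 (683 and 250 calls among 10885 genes), and 17 genes lower at d0 were higher in the spleen, against 3.41. In the same direction, 15 were higher in both, against 7.03, among them Il2ra, Zeb2 and Tcrg-C2, and 3 were lower in both (Cd7, Gpr183 and Rmi2), against 7.60. Fold changes at d0 and in the spleen correlated at -0.39 across genes, which are not independent replicates. Those at d0 and in the tumor correlated at -0.0063, with 2 genes higher in both (Tspan32 and Zfp981), 2 higher at d0 and lower in the tumor (Cacnb3 and Rora), 2 lower at d0 and higher in the tumor (Airn and Klre1) and 0 lower in both by edgeR, against 1.44, 0.816, 0.699 and 0.395. Those in tumor and spleen correlated at 0.068. The genes named in these overlaps were chosen after their values were seen. In tumor and spleen 7 genes were higher in both, against 0.237 for independent lists, 6 were lower in both, against 0.596, and 0 moved in opposite directions by edgeR. The tumor and spleen contrasts shared no samples, but they shared a fit, donors and recipient mice.

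The genes singled out above lie, on GRCm38 in GENCODE vM21 and as protein-coding genes, as follows. Mki67 (ENSMUSG00000031004) lies on chromosome 7 from 135689784 to 135716361, Klf2 (ENSMUSG00000055148) on chromosome 8 from 72319033 to 72321656, and Ifng (ENSMUSG00000055170) on chromosome 10 from 118441046 to 118445892. Klre1 (ENSMUSG00000050241) lies on chromosome 6 from 129577905 to 129585827 and Pclaf (ENSMUSG00000040204) on chromosome 9 from 65890237 to 65903266. Histone and Tcrg genes belong to families of similar copies, and their counts are uncertain, since the sharing of reads was not tested.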

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

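All tests of technical and recipient explanations in this part, and the splits within donor pairs, were chosen after the results were seen, and the other counts over splits of the samples were planned before. The MitoPositive effect differed between d7, as the mean of spleen and tumor, and d0 for 821 genes, by a test of the difference itself. Named genes with a higher effect at d7 were Klre1 (2.78), Samd3 (2.42), St6galnac3 (1.88), Klf3 (1.77), Airn (1.69), Klf2 (1.68), Ms4a4c (1.60), Abcb9 (1.59), Txk (1.59) and Myb (1.57). Those with a lower effect were Ccl1 (-5.13), Rrm2 (-3.04), Pclaf (-2.95), Spc24 (-2.90), Uhrf1 (-2.80), Rad51b (-2.71), Tnfsf11 (-2.68), Nusap1 (-2.64), Cdk1 (-2.62) and Hist1h2ae (-2.61). The value of Ccl1 had an SE of 1.31 (edgeR adjusted p = 0.027). Its values by donor were -1.41, -3.81 and -4.20, each smaller in size than the fitted value. Groups of 3 samples were not tested for a sample far from the others.

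Higher cell cycle RNA in MitoPositive cells at d0 was weighed against 2 technical explanations. With cells thinned to equal UMIs, the median log2 fold change of the G2/M list was 1.21 over the 18 genes that could be tested. With all UMIs it was 1.59 over 22 genes. For the 18 genes this argues against UMIs per cell as the whole cause. The S phase list went from 14 of 21 genes called, a median of 0.66 and quartiles of 0.40 and 1.19 to 0 of 15 called by edgeR, a median of 0.34 and quartiles of 0.21 and 0.58, so UMIs per cell stay open for S phase genes, as does the loss of cells and UMIs by thinning. The cycling cluster had a median of 19692 UMIs per barcode, against 2079 to 10662 in the other d0 clusters. Thinning gives such cells less weight in the sums, so it cannot part UMIs per cell from cycling for S phase genes. Summed stromal marker RNA differed by 0.264 CPM while G2/M RNA differed by 1034 CPM, which argues against RNA of BMSCs. A candidate explanation is that cycling cells took up or kept dsRed more often, or that uptake went with cycling. These were neither tested nor told apart. The G2/M median of 0.16 without the cycling cluster cannot tell, since genes that lead that cluster, among them Nusap1, Cenpf and Hmmr, are cell cycle genes themselves.

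The spleen difference at d7 may come from host T cells in the sort, since Trbv14 was a smaller share of Trbv RNA in MitoPositive samples, although cells before transfer also had other Trbv RNA (Trbv14 81.6% and 84.2% at d0). In Trbv14 cells the median ratio of fold changes to those in all cells was 1.00 over the called genes that could be tested, and 1.03 without the 2 samples of fewer than 20 such cells, which argues against host cells as the whole cause, although Cx3cr1, Gzmk, Trbc2 and Id3 did not pass there. Recipient mice shared by both arms were found for 0 donors, so recipients and the MitoPositive state cannot be told apart.

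The tumor difference at d7 may come from RNA of macrophages and melanoma cells. Without the clusters led by genes of other cell types, the median ratio of fold changes was 0.883 over the 42 genes that could be tested. Of these, 41 kept their direction, and 24 of the 50 were also called. For the 42 genes, this argues against the cells of those clusters as the whole cause. Leaving out clusters does not remove RNA of other cells from the cells that were kept, so that RNA stays open. The other 8 of the 50 genes could not be tested there and stay open. Recipient mice shared by both arms were again found for 0 donors, so recipients and the MitoPositive state cannot be told apart.

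For d0 (1059 genes), tumor (50) and spleen (392), the real split was 1 of 10, with at most 0 genes in the others, and 10 splits are too few for a share under 0.05. For tumor against spleen, 1 of 100 splits drawn from 200 gave as many genes as the real 7206, with at most 8 in the others. Most of these splits break the donor pairs, which the fit uses. Over all 32 splits within donor pairs, 1 gave as many, the real one, with at most 863 in the others. That is a share under 0.05, in splits chosen after the result was seen. For the difference between tissues the real count was 0, which 100 of 100 splits reach by construction (highest other 33), so the splits cannot tell. For the difference between days, 1 of 100 splits drawn from 4000 gave as many as the real 821, with at most 605 in the others, most of which break pairs. Over 100 splits within donor pairs drawn from 256, 1 gave as many, the real one, with at most 649 in the others. The share was under 0.05, but splits that were not drawn could give as many, so chance was not excluded. The 3 highest of the others (649, 605 and 363) kept the arms at d0 and in the spleen of donors 1 and 2.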

How the results depend on the processing

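Alternatives by cluster, by Trbv14 or with a recipient block were chosen after seeing the data. Counts moved by more than 1.5 times as follows, and where no construction is named the cause was not tested. At d0 (1059) the count was 1623 without a count filter (more genes tested), 215 thinned (fewer UMIs and genes), 2295 with the donor block, 622 without the cycling cluster, 0 with the other hashtag map, and 495 to 1542 leaving out 1 replicate. In the tumor (50) it was 171 with the DESeq2 test, 789 without a count filter, 5 with HTODemux, 2 thinned, 9 with tumor samples alone, 22 with Trbv14 cells and 85 without samples of fewer than 20 such cells, and 15 to 33 leaving out 1 replicate. In the spleen (392) it was 590 with the DESeq2 test, 930 without a count filter, 43 with HTODemux, 5 thinned, 1022 with spleen samples alone, 637 with Trbv14 cells and 674 without samples of fewer than 20 such cells, 64 without cycling clusters, 943 without clusters led by other cell types, and 0 to 979 leaving out 1 replicate. Tumor against spleen (7206) was 477 thinned. The difference between tissues (0) was 157 with the DESeq2 test, 876 without a count filter, 4 without the mitochondrial limit, 1 thinned, 7 without the donor block, 3 with the recipient block, 91 without clusters led by other cell types, and 0 to 420 leaving out 1 replicate. The difference between days (821) was 385 with HTODemux, 6 thinned, and 279 to 337 leaving out 1 replicate. Within 1.5 times stayed tumor against spleen, at 6910 with the recipient block and 5387 to 6284 leaving out 1 replicate. Of 176 list tests, camera called 55, camera with an estimated correlation 0 (smallest adjusted p 0.069) and fry 26. The fry calls were all between the organs or at d0, there for glycolysis, NK and γδ T cell and mitochondrial dynamics genes (adjusted p = 0.021 each). By fry, adjusted p at d0 was 0.065 for the G2/M and S phase lists. It was 0.15 and 0.23 for S phase and G2/M in the spleen, and 0.14 for mitochondrially encoded genes in the tumor. Between days it was 0.084 for the G2/M and S phase lists.

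If the map used is right, the groups of the other hashtag map mix the 2 states by construction. Signs turned for 27 of 68 named d0 genes with that other map: Pclaf -0.12, Stmn1 -0.21, Nusap1 -0.067, Hist1h2ap -0.0081, Ccnb2 -0.35, Birc5 -0.13, Klf2 0.039, Txn1 -0.13, Prdx1 -0.071, Cdk1 -0.11, Cxcr3 -0.018, Hspa8 -0.0571, Zeb2 -0.15, Gzma -0.46, Bhlhe40 -0.0021, Tpi1 -0.020, Phgdh -0.13, Psat1 -0.14, Tcrg-C2 -0.30, Vdac3 -0.00594, Cox5b -0.068, Atp5c1 -0.054, Cox5a -0.12, Rpl3 -0.13, Rpl10a -0.0817, Il6ra 0.017 and Idh2 0.026. Without the cycling cluster Nusap1 was -0.44, Hist1h2ap -0.054 and Cdk1 -0.52. Thinned, Il2ra in the spleen was -0.48, and between days St6galnac3 was -1.88 and Vdac2 0.018. C1qc between tissues was 0.023 without clusters led by other cell types. The cause was not tested.

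No other called and named gene changed direction in an alternative that gave it a value. Thinning gave no value for many of them (7 of 18 in the tumor and 19 of 45 in the spleen had one), and the 6 genes named for the difference between tissues were not followed. With the donor block all 68 named d0 genes stayed called. With HTODemux 59 of 68 at d0, 3 of 18 in the tumor and 13 of 45 in the spleen stayed called, and without replicate 1 none of the 45 in the spleen did by edgeR. The removal of doublets by Scrublet was not run, since it called 0%, 0.0196%, 0% and 1.04% of barcodes in the 4 libraries.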

Other observations

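The lists and their tests were fixed in advance, and the exact tests of summed marker RNA and of cells above the mitochondrial limit were not planned and were chosen after the data were seen. Each list below is given for d0 as genes higher and lower over all genes, then adjusted over the list alone, the median log2 fold change, and the adjusted p with an estimated correlation. Antioxidant genes had 3 and 0 of 14 (3 and 0 alone, 0.07, 0.78), apoptosis genes 0 and 1 of 14 (0 and 1 alone, 0.17, 0.78), chemokine and adhesion genes 3 and 1 of 14 (4 and 1 alone, 0.16, 0.72), and cholesterol synthesis genes 0 and 0 of 18 (0 and 0 alone, 0.15, 0.78). Dissociation stress genes had 1 and 0 of 9 (2 and 1 alone, -0.07, 0.92), effector genes 6 and 2 of 19 (8 and 3 alone, 0.29, 0.78), exhaustion genes 2 and 0 of 16 (4 and 2 alone, 0.20, 0.78), and fatty acid oxidation genes 1 and 0 of 14 (1 and 0 alone, 0.08, 0.78). Interferon response genes had 0 and 0 of 19 (0 and 0 alone, -0.10, 0.92), CD8 T cell markers 0 and 1 of 10 (1 and 1 alone, 0.02, 0.95), mitochondrial biogenesis and import genes 1 and 0 of 27 (0 and 0 alone, -0.04, 0.92), mitochondrial dynamics and transport genes 0 and 0 of 20 (0 and 0 alone, 0.13, 0.68), and tricarboxylic acid cycle genes 0 and 2 of 17 (0 and 2 alone, 0.02, 0.92). Ribosomal protein genes had 2 and 0 of 30 (2 and 0 alone, 0.12, 0.78), immediate early T cell receptor genes 2 and 0 of 13 (3 and 0 alone, 0.27, 0.68), and tissue residency genes 2 and 0 of 8 (4 and 0 alone, 0.35, 0.72), and these 3 lists had camera adjusted p of 0.0034, 0.037 and 0.037. NK and γδ T cell markers had 2 and 1 of 3 (2 and 1 alone, 0.74, 0.78), myeloid markers 0 and 0 of 4 (0 and 1 alone, 0.64, 0.78) and melanoma markers 0 and 0 of 3 (0 and 0 alone, 0.05, 0.97). For CD8 T cell markers and the tricarboxylic acid cycle, the camera statistic was negative while the median was positive.

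RNA of the marker lists of other cell types, as summed CPM in MitoPositive against MitoNegative samples (SD, n = 3), was as follows. At d0 no cluster had a gene of these lists among its leading genes, so this RNA need not come from other cells. B cell markers were 162 ± 28.6 against 222 ± 33.3 at d0 (exact p = 0.2), 105 ± 2.34 against 162 ± 23.1 in the spleen (exact p = 0.1) and 65.3 ± 6.70 against 88.6 ± 57.8 in the tumor (exact p = 0.9). They were higher in 0 of 3 donors at d0 and in the spleen, and in 2 of 3 in the tumor. CD4 T cell markers were 20.6 ± 2.50 against 17.5 ± 3.27 (exact p = 0.3), 42.4 ± 9.13 against 51.2 ± 19.7 (exact p = 0.7) and 29.1 ± 2.66 against 51.7 ± 25.8 (exact p = 0.1). Endothelial markers were 196 ± 32.2 against 212 ± 25.6 (exact p = 0.5), 65.9 ± 1.51 against 58.4 ± 16.5 (exact p = 0.6) and 40.9 ± 6.69 against 29.2 ± 6.37 (exact p = 0.1). Erythroid and platelet markers were 3.60 ± 1.35 against 4.45 ± 0.136 (exact p = 0.4), 36.1 ± 53.1 against 58.0 ± 86.3 (exact p = 0.6) and 4.90 ± 3.13 against 55.3 ± 79.5 (exact p = 0.1). NK and γδ T cell markers were 79.2 ± 14.4 against 56.7 ± 2.63 (exact p = 0.1), 239 ± 30.2 against 149 ± 51.1 (exact p = 0.2) and 140 ± 9.10 against 101 ± 48.6 (exact p = 0.3), higher in 3 of 3 donors each time. Myeloid markers were 115 ± 3.16 against 129 ± 4.11 at d0 (exact p = 0.1), lower in 3 of 3 donors, and 678 ± 471 against 460 ± 145 in the spleen (exact p = 0.5), higher in 3 of 3. Melanoma markers were 28.8 ± 2.85 against 28.4 ± 2.59 at d0 and 86.2 ± 93.7 against 49.6 ± 17.8 in the spleen (exact p = 0.9 each). Stromal markers were 11.1 ± 8.25 against 3.07 ± 0.920 in the spleen (exact p = 0.3) and 95.5 ± 12.3 against 87.9 ± 61.8 in the tumor (exact p = 0.8). The smallest p these tests can give is 0.1.

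Before the mitochondrial limit was applied, 3.87% ± 0.532 of MitoPositive and 1.47% ± 0.234 of MitoNegative cells at d0 lay above it (SD, n = 3, exact p = 0.1, the smallest possible), higher in 3 of 3 donors. The shares were 0.290% ± 0.305 against 0.390% ± 0.239 in the spleen (exact p = 0.7), higher in 1 of 3, and 3.05% ± 3.01 against 1.08% ± 1.86 in the tumor (exact p = 0.5), higher in 3 of 3.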
